A study of Macaca mulatta with 11 samples.

How the data were processed

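Total RNA from 11 cultures of mesenchymal stem cells grown from the marrow of rhesus monkeys was analysed on 1 array each. Per the labels' protocols, marrow was flushed from the long bones of fetal and newborn donors and aspirated from infant and adult donors. Mononuclear cells were enriched on a gradient and plated, non-adherent cells were discarded, and cells were collected before confluence at passage 2. RNA was labelled with biotin in a one-cycle protocol. The deposited values are intensities per probe set processed by RMA, per the submitters' processing notes, which give no version. RMA corrects background, normalises between arrays and summarises the probes of a set, so that differences in total brightness between arrays are removed before deposit. Probe-level signals and a detection call were not used here. The deposited intensity was on a linear scale, with all values above 0, the lowest at 75.3 and array maxima between 27962 and 36519, so log2 was taken first.

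Human probes were used for monkey RNA by the probe annotation, so that the level of a probe set also reflects how well its probes match the monkey sequence, and levels of different probe sets were compared only to tell dim from bright ones and to choose 1 probe set per gene. Of 22215 probe sets, 19065 had 1 gene symbol in the table used, 1043 had several and 2107 had none. Genes were named only from probe sets with 1 symbol. There were 0 control probe sets. No pair of arrays held identical values.

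Groups were taken from the titles (fetal 4, infant 4, adult 3). Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 11 arrays, with empirical Bayes moderation (lmFit and eBayes), and pairwise contrasts and an F test over the 3 groups were tested two-sided. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets. Newborn and gestation day 120 arrays were compared in a fit with 1 mean per stage, with 2 arrays each. No array weights, blocks or filters were used for these. Adjusted p-values in the report without another name are limma's.

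Gene lists, 30 in number with 713 entries of which 621 were measured, were written before the data were examined and tested with camera at a preset inter-gene correlation of 0.01. Each of 11963 genes was represented by its probe set with the highest mean. Adjusted p-values are over the 30 lists. Camera with an estimated correlation and fry, a rotation test of each list by itself, were alternatives. The median change, the mean change and the test had the same sign for every called list. Among lists not called between fetal and adult arrays the signs differed for collagens, other matrix proteins, secreted senescence-associated factors, mesenchymal stem cell surface markers, HOX genes, limb transcription factors, WNT signalling, sex-linked genes and the erythroid, endothelial and neural markers, with adjusted p of at least 0.353.

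Named genes followed a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls per comparison among called probe sets with 1 symbol and no overlap between the groups, or the 5 genes of smallest p in each direction where none was called. It added up to 4 members of smallest p of each called list, up to 2 called members of other lists, and as identity genes ENG, THY1, NT5E, CD44, PTPRC, CD14, CD68, XIST and the globins. CD68 and some globins were measured only by probe sets with several symbols and are not reported here. For newborn against gestation day 120 it took the 3 genes of smallest p in each direction. The other called genes, RPS4Y1, the immunoglobulin light chains and the genes of the first component were chosen after their values were seen.

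The fits were tested on simulated data in which 200 of 22215 probe sets were shifted. A log2 shift of 1 was recovered for 90.0% of them between fetal and adult, 89.5% between infant and adult and 92.5% between fetal and infant groups, and a shift of 2 for 99.5% in each. All recovered shifts had the right direction, 7 to 11 unchanged probe sets were called, and with no shift 0 were called. The simulated noise was independent between probe sets and between arrays. It lacked the structure that the first principal component shows in the real arrays, so these values do not give the power or the error rate there.

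The titles share replicate numbers between groups. Deviations from the group means of infant and adult arrays of the same number correlated at 0.145, 0.131 and 0.204 across probe sets, all above 0.1, so that these numbers passed the check for pairs in that comparison. The comparison stayed without a block, as fixed before the data were examined, and the values with the block are given beside it. Infant array 2 nevertheless correlated best with adult array 1 (0.258). The first principal component also divides infant and adult arrays 1 and 2 from infant and adult arrays 3, and the check cannot tell pairs from that division. For fetal and adult arrays the correlations were 0.068, 0.043 and -0.096, and for fetal and infant arrays 0.116, 0.0077, 0.041 and 0.275, so that these numbers did not pass it.

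Alternatives fixed before the data were examined were median centring, quantile normalisation applied again, filters on dim and on flat probe sets, a trended and robust variance prior, array weights, 1 probe set per gene, the replicate block, a fit of only the groups compared, a change of at least 1.5-fold, leaving out the newborn arrays and leaving out each array in turn. Alternatives chosen after the data were examined were the side of the first principal component as a block, only the arrays on 1 side of it, adult arrays 1 and 2 left out, and the replicate block together with an estimated correlation. Scan dates and hybridisation batches were not given in the sources used here. Figures were drawn with matplotlib.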

Results

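Gene expression was measured in 11 cultures of bone marrow-derived mesenchymal stem cells, the adherent stromal cells of marrow that can form bone, fat and cartilage cells, established from rhesus monkeys (Macaca mulatta) of different ages. Each culture was hybridised to 1 oligonucleotide array annotated with human genes, which gave an intensity for each of 22215 probe sets. The titles placed 4 arrays in a fetal, 4 in an infant and 3 in an adult group. Fetal arrays 1 and 2 came from donors at gestation day 120, whereas fetal arrays 3 and 4 were titled fetal but came from newborn donors. Infant donors were aged 6, 6, 3 and 5 months for arrays 1 to 4, and adult donors were aged 7, 7 and 8 years for arrays 1 to 3. Median intensities lay between 164.9 and 169.7, and correlations between arrays on the log2 scale lay between 0.928 and 0.983. The number of arrays limited the precision. The labels do not state that arrays of one age came from different animals, so that p-values measured the spread between these cultures.

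ENG, CD44, THY1 and NT5E, which encode surface proteins of mesenchymal stem cells, did not pass the test over all genes between any age groups. ENG, the endoglin surface receptor, had mean log2 intensities of 9.09 ± 0.13 (SD, n = 4) in fetal, 9.03 ± 0.31 (SD, n = 4) in infant and 8.91 ± 0.23 (SD, n = 3) in adult arrays. CD44, the hyaluronan receptor, stood at 9.69 ± 0.24 (SD, n = 4), 9.49 ± 0.09 (SD, n = 4) and 9.14 ± 0.13 (SD, n = 3), and its fetal-to-adult difference of 0.55 did not pass the test (limma adjusted p = 0.132). THY1 lay between 8.16 and 8.37 in the group means and NT5E between 6.93 and 7.05. The NT5E means lay below the median of all log2 values, 7.38, so that its probe set may read too weakly to show a change. The list of 19 surface marker genes was not called between fetal and adult arrays (camera adjusted p = 0.429). Adjusted over the list alone 4 of them passed, 3 higher and 1 lower in fetal arrays, and fry's mixed test for changes in either direction gave an adjusted p of 0.00180. PTPRC, the leukocyte common antigen, and CD14, a monocyte marker, did not pass in any comparison, with adjusted p of at least 0.819 for both. The globin genes HBB, HBD, HBE1, HBQ1 and HBZ did not pass in any comparison either, with adjusted p of at least 0.666. XIST, the noncoding RNA of the inactive X chromosome, stood at 11.23 in adult array 3 and between 7.27 and 8.40 in the other 10 arrays. RPS4Y1, a Y-linked ribosomal protein gene chosen after its values were seen, stood at 7.81 in adult array 3 and between 11.3 and 12.2 in the others. The sex of the donors is not given in the sources used here, and no comparison was adjusted for it. A difference in sex between adult array 3 and the other arrays was not tested and may enter the comparisons with adults.

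The first principal component, which held 23.1% of the variance, divided the arrays across the age groups. Adult arrays 1 and 2 and infant arrays 1 and 2 lay at -18.7, -20.5, -19.6 and -16.1, and the other arrays lay between 6.70 and 19.5. The second component held 17.5% of the variance. On it the fetal arrays lay between -20.4 and 4.09, the infant arrays between -5.31 and 11.96, and the adult arrays between 7.84 and 23.4. Some probe sets of immunoglobulin genes, whose transcripts antibody-producing cells make, read higher in adult arrays 1 and 2 than in every other array. The brightest IGLC1 probe set, for a lambda light chain constant region, read 12.82 and 13.23 there, 9.10 in adult array 3 and at most 8.30 elsewhere. Other such probe sets did not, as with 1 of IGHM at 8.13 in adult arrays 1 and 2 and 8.40 in infant array 3.

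**Figure D1:**
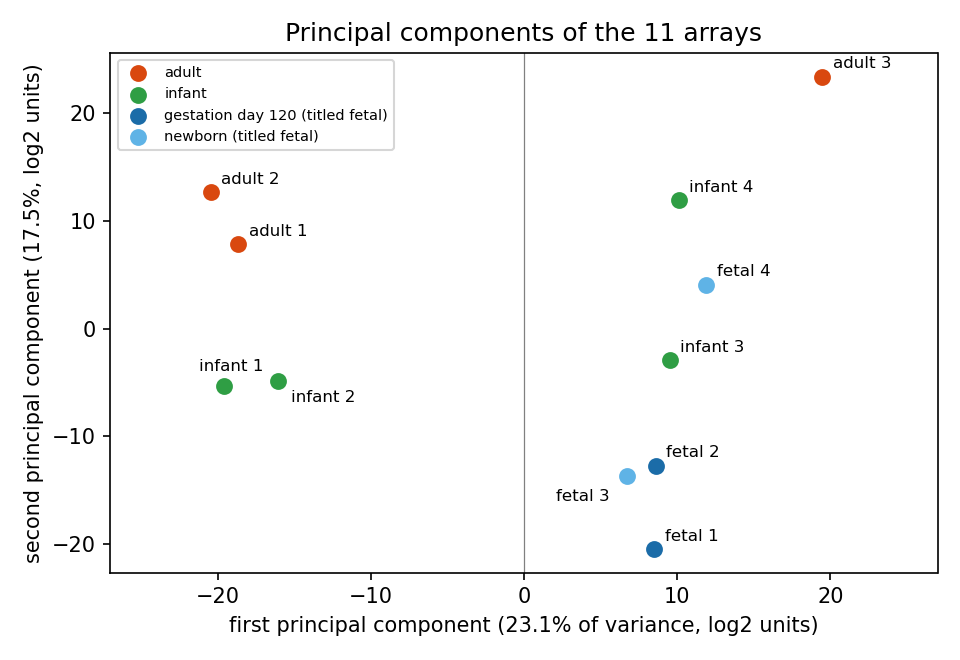
The first principal component of log2 intensity is on the horizontal axis and the second on the vertical axis, with 1 point per array coloured by donor stage. The first component separates adult arrays 1 and 2 and infant arrays 1 and 2, all at or below -16.1, from the other 7 arrays, all at or above 6.70.

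The comparison of fetal with adult arrays addressed how donor age relates to gene expression in these cells, and it gave the largest number of changed genes. CHI3L1, which encodes a secreted chitinase-like glycoprotein, fell by 3.53 on the log2 scale (SE 0.35), from 11.55 ± 0.78 (SD, n = 3) in adult to 8.02 ± 0.55 (SD, n = 4) in fetal arrays (adjusted p = 0.000892). Its brightest probe set read 12.59 in adult, 11.03 in infant and 9.69 in fetal arrays, and its remaining one differed by -0.46 without passing (adjusted p = 0.324). PTGDS, a prostaglandin D synthase, fell by 2.52 (SE 0.41, adjusted p = 0.0372), with its other 2 probe sets at -1.62 and -1.35 (adjusted p = 0.0667 and 0.108). SULF1, a heparan sulfate endosulfatase, fell by 1.78 (SE 0.23, adjusted p = 0.00768), with its other 2 at -1.18 and -0.12 (adjusted p = 0.179 and 0.823). The calcium-binding protein gene S100A4 was 3.87-fold higher in fetal arrays, at 10.82 ± 0.17 (SD, n = 4) against 8.87 ± 0.61 (SD, n = 3), with a log2 change of 1.95 (SE 0.30, adjusted p = 0.0273). AKR1B10, an aldo-keto reductase, rose 3.19-fold in fetal arrays, a log2 change of 1.67 (SE 0.21, adjusted p = 0.00758).

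The secreted ligand WNT5A rose by 1.42 on the log2 scale, the basement membrane protein NID2 by 1.37, the chromatin protein HMGA1 by 1.26, the transcriptional inhibitor ID3 by 1.20, the neural cadherin CDH2 by 1.12 and the collagen VI chain COL6A1 by 1.09 in fetal arrays, with adjusted p between 0.0198 and 0.0466. COL6A1 had 7 other probe sets, of which 5 went the same way and none passed. The other probe set of WNT5A differed by 0.53, that of HMGA1 by 0.084 and that of CDH2 by 0.74, and none of these passed (adjusted p = 0.275, 0.909 and 0.0984). The RNA-binding protein gene IGF2BP3 rose by 0.82 (SE 0.14, adjusted p = 0.0381), and its other 2 probe sets differed by 0.18 and 0.052 (adjusted p = 0.641 and 0.938). Among genes that fell, the microfibril protein MFAP5 fell by 1.41, the smooth muscle actin ACTG2 fell by 1.32, MXRA7 fell by 1.02 and dystrophin, DMD, fell by 1.02, with adjusted p between 0.00489 and 0.0381. The other 2 probe sets of MFAP5 differed by -0.13 and -0.39 (adjusted p = 0.805 and 0.363) and those of DMD by -0.22 and -0.13 (adjusted p = 0.690 and 0.812). IGHM, an immunoglobulin heavy chain gene, fell by 1.60 (SE 0.27, adjusted p = 0.0389), and its values of 9.13 and 9.34 in adult arrays 1 and 2 stood apart from 7.71 in adult array 3 and at most 7.44 elsewhere. Its other 4 probe sets did not pass. Other genes that passed were TM4SF1, CDC25B and STX1A, which rose, and SLC47A1, BBLN, NTRK2, CNN1 and PLPP1, which fell.

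In all, 29 probe sets passed an adjusted p of 0.05, 14 higher and 15 lower in fetal arrays, and they named 25 genes. Of these probe sets 1 carried several symbols and 2 were unnamed here. An unadjusted p under 0.05 was reached by 1990 probe sets. The fetal and adult arrays did not overlap for 1794 probe sets, 8.08% of all, where chance gives 5.71%. Of the 3 probe sets each of CHI3L1 and MFAP5, 2 and 1 passed in all 7 fits that left out 1 fetal or adult array, and that of AKR1B10 passed in 6. The count was 4 without adult array 1, adult array 2 or fetal array 2, 7 without fetal array 1 and 9 without fetal array 3, but 153 without adult array 3, with all 29 among them, and 120 without fetal array 4. With adult arrays 1 and 2 left out, an alternative chosen after the data were seen, all 29 probe sets kept their direction. That was fixed beforehand, since the fetal and adult arrays did not overlap for any of the 29. The fit also left 1 adult array, which was assumed to vary like the arrays of the other groups.

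**Figure D2:**
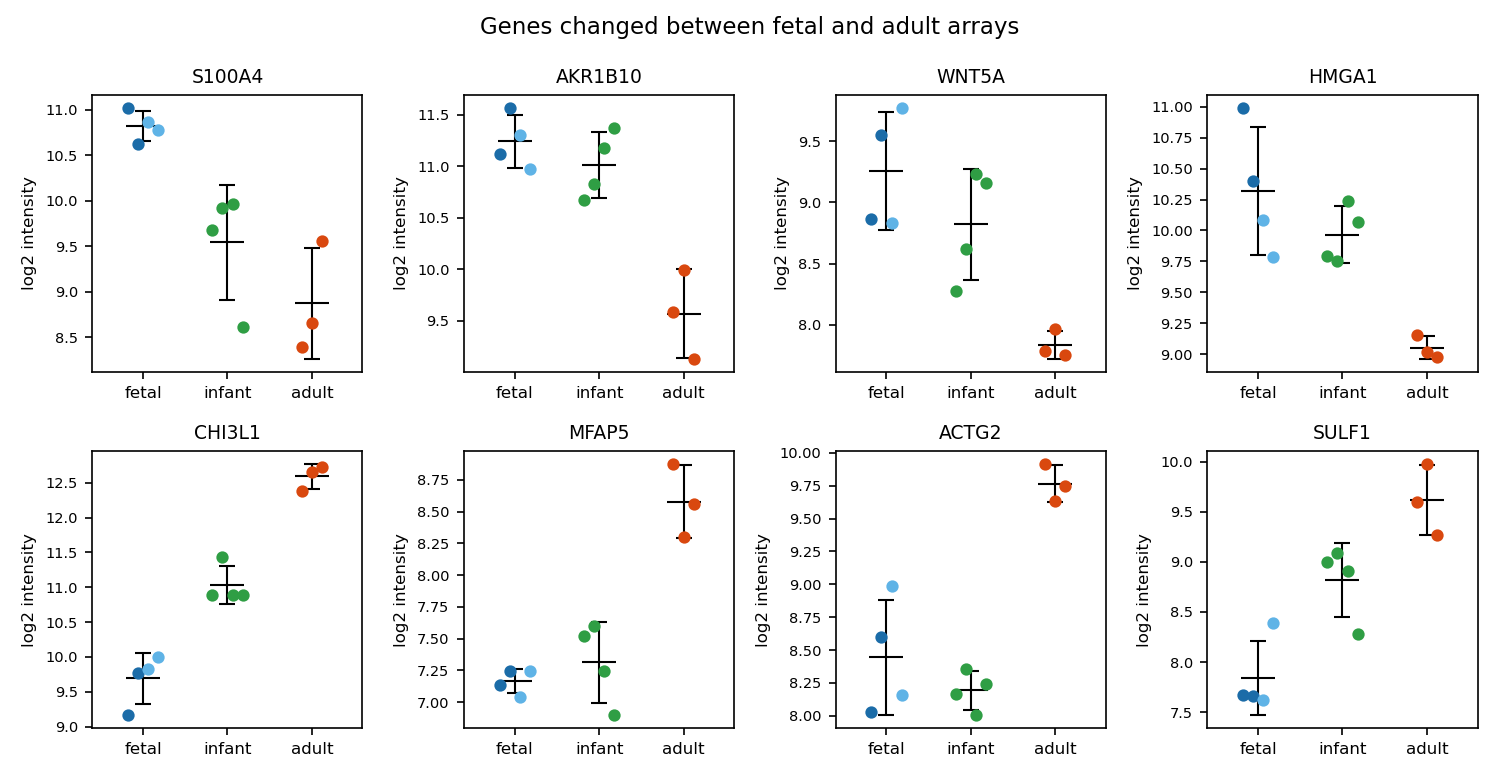
Log2 intensity of 8 genes is plotted for each array, with dark blue for gestation day 120, light blue for newborn, green for infant and orange for adult donors, and with horizontal bars and error bars for the group mean and SD. S100A4, AKR1B10, WNT5A and HMGA1 were higher in every fetal array than in every adult array, and CHI3L1, MFAP5, ACTG2 and SULF1 were lower.

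Genes of the contractile apparatus formed the gene list with the smallest p between fetal and adult arrays. Of 17 measured smooth muscle and contractile genes 14 were lower in fetal arrays, with a median change of -0.60 (camera adjusted p = 4.82e-10, and adjusted p = 0.168 with an estimated correlation). Only ACTG2 and the calponin gene CNN1, which fell by 0.84 (SE 0.11, adjusted p = 0.00815), passed over all genes, whereas 11 passed when adjusted over the list alone, all lower. MYL9 and TAGLN, a myosin light chain and transgelin, differed by -0.75 (adjusted p = 0.0829) and -0.72 (adjusted p = 0.149). The mean deviation of the contractile list was between -0.54 and -0.24 in fetal arrays 1 to 3, 0.10 in fetal array 4 and between 0.22 and 0.43 in adult arrays. The cartilage list was also called lower, with 13 of 18 members lower (camera adjusted p = 0.0204, and adjusted p = 0.274 with an estimated correlation). Its only member to pass, over all genes or adjusted over the list alone, was CHI3L1, and SOX5 and COL2A1 differed by -0.34 and -0.16 without passing (adjusted p = 0.407 and 0.722), and COL2A1 by -0.09 without adult array 3 and -0.08 without fetal array 3. Without adult array 3 the cartilage call was lost, at an adjusted p of 0.4995.

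Growth-related lists were called higher in fetal than in adult arrays. For mitosis and DNA replication, however, fetal array 4 did not lie above every adult array. The fetal growth and imprinted genes had 14 of 20 members higher (camera adjusted p = 0.000525, and adjusted p = 0.0745 with an estimated correlation). Its members HMGA1 and IGF2BP3 passed over all genes, and 7 passed adjusted over the list alone, of which 6 were higher. The mean deviation of this list was between 0.11 and 0.22 in fetal arrays and between -0.19 and -0.16 in adult arrays. MEG3 and PLAGL1, imprinted genes, were higher by 0.61 (adjusted p = 0.0831) and 0.71 (adjusted p = 0.165), and 1 other probe set of each went the opposite way. The mitosis list had 25 of 32 members higher (camera adjusted p = 0.000139, and adjusted p = 0.756 with an estimated correlation), and the DNA replication list 25 of 31 (camera adjusted p = 0.000833, and adjusted p = 0.756 with an estimated correlation). No member of either passed, over all genes or adjusted over the list alone. CDC20, an activator of anaphase, was higher by 1.26 (adjusted p = 0.358) and the helicase subunit MCM5 by 0.92 (adjusted p = 0.358). The mean deviation of the mitosis list was between 0.30 and 0.33 in fetal arrays 1 to 3, -0.22 in fetal array 4 and between -0.24 and -0.04 in adult arrays. That of the DNA replication list was between 0.24 and 0.26 in fetal arrays 1 to 3 and -0.20 in fetal array 4, below all adult arrays, at -0.19 to -0.03.

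Glycolysis genes lay higher in fetal arrays in 18 of 21 cases (camera adjusted p = 0.000158, and adjusted p = 0.199 with an estimated correlation). None passed over all genes and 5 passed adjusted over the list alone, all higher. The hexokinase HK1 was higher by 0.49 (adjusted p = 0.282) and the pyruvate kinase PKM by 0.56 (adjusted p = 0.245). Heat shock and unfolded protein response genes were higher in 16 of 21 cases (camera adjusted p = 0.0428, and adjusted p = 0.284 with an estimated correlation), and none passed over all genes or adjusted over the list alone. The chaperones HSPE1 and HSPD1 were higher by 0.58 and 0.43 (adjusted p = 0.306 and 0.414), and HSPD1 by 0.20 without adult array 3. That call was lost without adult array 1 (adjusted p = 0.0937), adult array 3 (0.183), fetal array 2 (0.0980) or fetal array 3 (0.0690).

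Of 30 lists 7 were called between fetal and adult arrays, 5 higher and 2 lower, and none held with an estimated correlation. Markers of other cell types were not called, with adjusted p of 0.353 for macrophages and leukocytes, 0.965 for erythroid cells, 0.437 for endothelium, 0.429 for skeletal muscle and 0.552 for neural and glial cells. For the erythroid, endothelial and neural lists the median change had the opposite sign from the test. HOX genes, which keep the positional identity of connective tissue cells, were not called (camera adjusted p = 0.737), although fry's mixed test for changes in either direction gave an adjusted p of 0.0244. Fetal and newborn marrow had been flushed from long bones and the other marrow aspirated, so the collection method and the fetal group cannot be told apart.

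Infants differed from adults in 4 genes, each of which had also changed in the fetal arrays. AKR1B10 was higher in infant arrays, at 11.01 ± 0.32 (SD, n = 4) against 9.57 ± 0.43 (SD, n = 3), a log2 change of 1.44 (SE 0.21, adjusted p = 0.0405). ACTG2 fell by 1.57 (SE 0.19, adjusted p = 0.0106), from 9.77 ± 0.14 (SD, n = 3) to 8.19 ± 0.15 (SD, n = 4). CHI3L1 fell by 1.57 (SE 0.19, adjusted p = 0.0106) and MFAP5 fell by 1.27 (SE 0.17, adjusted p = 0.0176). The groups of arrays did not overlap for any of the 4.

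An unadjusted p under 0.05 was reached by 1374 probe sets between infant and adult arrays, and the arrays did not overlap for 4.98% of probe sets, where chance gives 5.71%. The replicate numbers in the titles passed the check for pairing, which cannot tell pairs from the division on the first component. The comparison had been fixed without a block before the data were examined. With the replicate block 9 probe sets passed in place of 4, of which 2 were higher and 7 lower. Without adult array 1 or infant array 3 the count was 0, and without adult array 3 it was 55.

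Immediate early genes, which respond within minutes to growth signals or stress, lay higher in infant than in adult arrays in all 19 members, with a median change of 0.58 (camera adjusted p = 3.33e-09, and adjusted p = 0.631 with an estimated correlation). None passed over all genes or adjusted over the list alone. NR4A3, FOS and EGR1 were higher by 1.16 (adjusted p = 0.551), 0.96 (adjusted p = 0.712) and 0.92 (adjusted p = 0.667). Without adult array 3 FOS and EGR1 stood at 0.56 and 0.58. Smooth muscle and contractile genes were lower in 14 of 17 cases (camera adjusted p = 0.000754, and adjusted p = 0.631 with an estimated correlation). ACTG2 alone passed over all genes, and 3 passed adjusted over the list alone, all lower, while CNN1 was lower by a log2 change of -0.61 (adjusted p = 0.146). Without adult array 3 the contractile call was lost, at an adjusted p of 0.0620. Of 30 lists 2 were called, 5 without infant array 4, and 8 with the replicate block. With that block immediate early, mitosis, DNA replication, glycolysis and ribosomal protein genes were called higher, and contractile genes, collagens and other matrix proteins lower. With the block and an estimated correlation, chosen after the results were seen, none of these 8 held (adjusted p from 0.441 to 0.668).

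**Figure D3:**
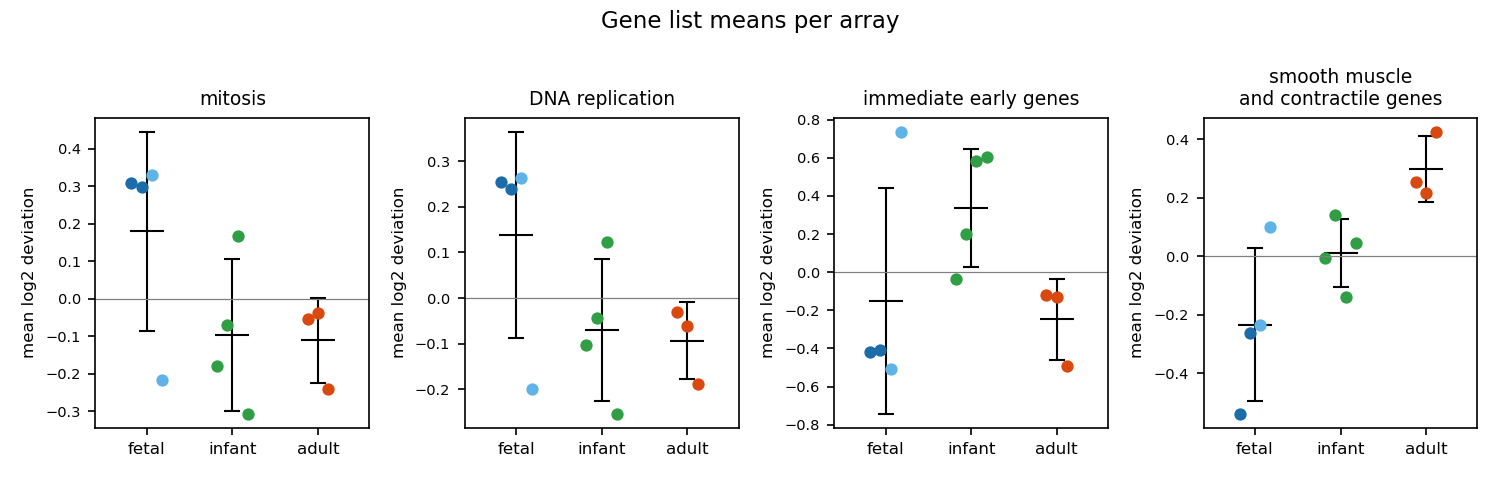
For 4 gene lists, each point is the mean over members of the log2 deviation from the gene's mean over all arrays, in 1 array, with dark blue for gestation day 120, light blue for newborn, green for infant and orange for adult donors, and bars for the group mean and SD. Fetal array 4 lies at -0.22 for mitosis and 0.74 for immediate early genes, apart from the other 3 arrays titled fetal.

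No probe set passed between fetal and infant arrays, with 1527 at an unadjusted p under 0.05 in limma. CHI3L1 came closest, with a log2 difference of -1.33 (SE 0.18, adjusted p = 0.0556), from 11.03 ± 0.27 (SD, n = 4) in infant to 9.69 ± 0.37 (SD, n = 4) in fetal arrays. FOS, a subunit of the AP-1 transcription factor, stood at 9.77 ± 0.76 (SD, n = 4) in fetal and 11.61 ± 0.29 (SD, n = 4) in infant arrays, and the kindlin gene FERMT2 at 8.21 and 9.07. The transcription factor GATA6 was higher in fetal arrays by 0.79, the WNT receptor FZD2 by 0.99 and MICAL2 by 1.08. These genes, together with STX1A, LUC7L3, CD99 and CFD, had the smallest p in either direction after CHI3L1, with an adjusted p of 0.197 each.

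Of 30 lists 11 were called between fetal and infant arrays, 6 higher and 5 lower, and none held with an estimated correlation. Immediate early genes were lower in 17 of 19 cases (camera adjusted p = 5.14e-06, and adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone 4 of them passed, 3 lower and 1 higher, and none over all genes, with EGR1 at -1.22, JUN at -1.01 and FOSL1 at 0.46. The mean deviation of this list was between -0.51 and -0.41 in fetal arrays 1 to 3, 0.74 in fetal array 4 and between -0.04 and 0.60 in infant arrays. Ribosomal protein genes were lower in 24 of 26 cases (camera adjusted p = 6.58e-05, and adjusted p = 0.526 with an estimated correlation), with RPS7 at -0.64 and RPS14 at -0.52, and no member passed. The mean deviation of the ribosomal list was 0.20 and 0.33 in infant arrays 1 and 2. In infant arrays 3 and 4, at -0.06 and -0.09, it lay within the fetal range of -0.16 to -0.04. With the side of the first component as a block the ribosomal list turned to higher in fetal arrays, at a shift of 0.060 over the other genes (adjusted p = 0.157).

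The mitosis list was higher in fetal than in infant arrays in 27 of 32 cases (camera adjusted p = 6.58e-05, and adjusted p = 0.444 with an estimated correlation), with CCNB1 at 0.89 and TOP2A at 0.41. DNA replication genes were higher in 25 of 31 cases (camera adjusted p = 0.00225, and adjusted p = 0.444 with an estimated correlation), with MCM6 at 0.73. Fetal array 4 lay below the mean over all arrays for both lists, at -0.22 and -0.20, and also for sterol synthesis, at -0.07, and glycolysis, at -0.03. Sterol synthesis genes were higher in 14 of 15 cases (camera adjusted p = 0.00163, and adjusted p = 0.276 with an estimated correlation), with NSDHL at 0.62 and FDPS at 0.29. Fetal growth and imprinted genes were higher in 16 of 20 cases (camera adjusted p = 0.00645, and adjusted p = 0.273 with an estimated correlation), and 2 passed adjusted over the list alone, with MEG3 at 0.58 and IGF2BP3 at 0.60. Collagen genes were higher in 13 of 18 cases (camera adjusted p = 0.00343, and adjusted p = 0.444 with an estimated correlation), with 3 passing adjusted over the list alone, all higher, and COL6A2 at 0.83 and COL16A1 at 0.86. Glycolysis genes were higher in 16 of 21 cases (camera adjusted p = 0.0167, and adjusted p = 0.342 with an estimated correlation), with LDHA at 0.30. No member of these lists passed over all genes. The collagen call was lost without fetal array 4 (adjusted p = 0.197), the DNA replication call without infant array 4 (0.0724), and the glycolysis call without fetal array 1 (0.0508), fetal array 2 (0.0538) or infant array 4 (0.128).

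Smooth muscle and contractile genes were lower in fetal than in infant arrays in 12 of 17 cases (camera adjusted p = 0.000169, and adjusted p = 0.342 with an estimated correlation), with the myosin kinase MYLK at -1.09 and the actin gene ACTA2 at -0.74, which was -0.41 without fetal array 1. The mean deviation of this list was 0.10 in fetal array 4, between -0.54 and -0.24 in fetal arrays 1 to 3 and between -0.14 and 0.14 in infant arrays. For the cartilage list it was 0.03 in fetal array 4 and between -0.16 and -0.12 in fetal arrays 1 to 3. The cartilage list was lower in 12 of 18 cases (camera adjusted p = 0.0292, and adjusted p = 0.324 with an estimated correlation), and CHI3L1 alone passed adjusted over the list alone. Interferon response genes were lower in 19 of 27 cases (camera adjusted p = 0.0359, and adjusted p = 0.379 with an estimated correlation), with CXCL10 at -0.29, which was -0.15 without infant array 2, and OAS2 at -0.29. No member of these lists passed over all genes. The cartilage call was lost without fetal array 2 (adjusted p = 0.0622), fetal array 3 (0.0630) or infant array 4 (0.110), and the interferon call without fetal array 2 (0.167), fetal array 4 (0.0974), infant array 1 (0.228) or infant array 2 (0.127). HOX genes were not called between fetal and infant arrays (camera adjusted p = 0.283). The count of probe sets was 21 without fetal array 4 and 4 without infant array 3. It was 5 when both newborn arrays were left out, and CHI3L1 was the single call when 1 probe set per gene was tested.

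Over the 3 age groups together, 8 probe sets changed by the F test of limma, those of ACTG2, CNN1, AKR1B10, MFAP5, SULF1 and the neurotrophin receptor NTRK2, and 2 of the 3 for CHI3L1. Adjusted p ranged from 4.19e-05 for CHI3L1 to 0.0376 for NTRK2, and 1780 probe sets had an unadjusted p under 0.05. The count was 2 without adult array 1, 4 without adult array 2, 5 without fetal array 1, 2 or 3, 15 without infant array 4, 18 without infant array 3, 67 without fetal array 4 and 95 without adult array 3.

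For CHI3L1 the infant mean lay between the other group means, and this held for 28 of the 29 probe sets called between fetal and adult arrays. Its median position was 0.583 on a scale where 0 is the adult and 1 the fetal mean. Probe sets chosen for a wide gap between fetal and adult means leave most other means in between, and no chance value was computed for either number. The log2 changes of fetal and of infant arrays against the same adult arrays correlated at 0.647 across probe sets, which are not independent replicates. Simulated unchanged groups against shared adults gave 0.571. The covariance was 0.0240 against a simulated 0.0137, a difference of 0.0103. Both changes had the same sign for 70.1% of probe sets, against a simulated 69.4%. The simulation gave each probe set 1 spread for all groups and no structure between arrays. A wider spread among the adult arrays alone would raise the simulated values, so these differences do not establish a change shared by fetal and infant arrays. All 4 probe sets called in infants were among those called in fetal arrays, where independent lists of those lengths share 0.00063 higher and 0.0020 lower ones. That expectation leaves out the adult arrays common to both comparisons, which were too few to split.

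Within the arrays titled fetal, no gene passed between newborn and gestation day 120 donors, with 402 probe sets at an unadjusted p under 0.05 in limma and a smallest adjusted p of 1. The genes with the smallest p were ADAM12, FOSL2 and RAP2C, higher in newborns by 0.86, 0.99 and 0.50, and NAA35, CDH2 and GAP43, at -0.61, -0.60 and -1.22, the last of which was -0.72 without fetal array 1. CDH2 thus stood at 8.97 ± 0.13 (SD, n = 2) at gestation day 120 and 8.37 ± 0.12 (SD, n = 2) in newborns. Without fetal array 3 the count was 2, with fetal array 4 as the single newborn array.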

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

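The tests on fetal array 4, with the swap of labels tested a second time in another way, on cross-hybridisation, on donor age group and on an unrecorded batch were chosen after the results were seen. The verdicts on the newborn stage, the swap of labels and a few strongly varying genes were changed to undecided after they were seen. The tests on fetal array 4 took the place of tests already run on the probe sets changed between fetal and adult arrays. These had given median ratios of the changes to those over all adults of 1.01 without adult array 3 and 0.987 against it alone, and a mixed fry adjusted p of 0.389 for HOX genes between fetal and infant arrays.

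An array far from the other 3 of its group was found in 21 of 262 groups of 4 tested, for 17 genes and 4 lists, where chance flags about 1 in 20 groups, which is 13. Fetal array 4 stood apart for 11 of these. Its mean log2 deviation was -0.217 for the mitosis list, -0.199 for DNA replication, -0.133 for oxidative phosphorylation and 0.737 for immediate early genes. Its log2 intensity was 8.392 for SULF1, 8.122 for CDC20, 9.449 for HSPE1, 8.101 for HBB, 10.192 for NR4A3, 8.555 for FERMT2 and 7.651 for NSDHL. Fetal array 1 stood apart at 7.167 for HAPLN1 and 7.181 for HBE1. Infant array 2 stood apart at 11.437 for CHI3L1 and 7.192 for NAA35, and infant array 4 at 9.027 for HSPE1 and 7.742 for GAP43. Infant array 1 stood apart at 7.526 for COL9A2, 9.744 for HK1, 8.76 for PDIA4 and 7.144 for PTPRC. For HBE1 and NAA35 the other 3 arrays of the group held an identical value, so that a gap of any size would have been flagged. The chance value of 13 does not allow for such ties.

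Fetal array 4 had the lowest mitosis and the highest immediate early values of the arrays titled fetal. The newborn stage of its donor stays open, since the lists were picked because fetal array 4 lay far from the others, which fixed that fetal array 3, also newborn, lay nearer to it in 0 of 4 lists. A swap of labels with infant array 3 stays open too: on 100 genes chosen without both, where 0 is the infant and 1 the fetal mean, infant array 3 lay at 0.568 and fetal array 4 at 0.207, with SDs of 0.237 and 0.254 over the other 15 pairs left out. Those pairs include fetal array 4, at 0.15 to 0.30 against 0.67 to 0.92 for fetal arrays 1 to 3, which widens the SD of 0.254. Infant array 4 also lay at 0.52 to 0.56 with fetal array 1, 2 or 3 left out, but at 0.12 with fetal array 4 left out. Infant array 3 had the highest infant mitosis mean, 0.169, whereas its immediate early mean of 0.58 lay far above fetal arrays 1 to 3, which a first test had taken as evidence against the swap, and the fetal growth list, at 0.11 in fetal array 4 and 0.02 in infant array 3, lay between fetal arrays 1 to 3, from 0.17 to 0.22, and the other infant arrays, from -0.14 to 0.01, with fetal array 4 above every infant array. The growth state of that culture may account for the pattern and stays open, as its mitosis mean lay at -0.53 relative to fetal arrays 1 to 3 and no density at harvest is given per culture; differences between donors stay open and untested.

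Some immunoglobulin probe sets were high in adult arrays 1 and 2. The brightest of IGLC1 lay above its median over arrays by 4.53 and 4.94 and that of IGKC by 1.77 and 2.30. Other probe sets of these genes lay near their medians, such as 1 of IGLC1 at 0.014 and 0.027 and 1 of IGKC at -0.17 and -0.092. For antibody-secreting cells, the median of 14 plasma cell genes lay at the 6.13 percentile of random lists in adult array 2 and at 65.5 in adult array 1, which met the bound set beforehand for excluding them. That verdict was changed to undecided after it was seen, because 8 of the 14 genes lie below the median level, where a small share of such cells could stay hidden, while the genes differed, with JCHAIN at 7.05 and 7.49 there and at most 6.97 elsewhere, and FKBP11, the brightest, at 9.59 and 9.32 there and 10.33 in adult array 3. A carry-over of blood cells stays open, with the 22 leukocyte genes, 1 of them also in the other list, at the 84.06 and 97.57 percentiles, although non-adherent cells had been discarded. A single cross-hybridising transcript first came out in favour, with the brightest IGHM probe set 0 above its median, and was likewise changed to undecided because another IGHM probe set stood 1.88 and 2.09 above, so that this depends on the probe set.

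The first principal component divided adult arrays 1 and 2 and infant arrays 1 and 2 from the rest. Donor age group is argued against as its source, since adult arrays lay at -20.5, -18.7 and 19.5, whereas the share of 0.353 of all regroupings with as much of the component between groups restates the division and was not used. Whether a few strongly varying genes carry it stays open, since the 500 probe sets left out were picked for their loading on it, so that the 8 of 11 arrays that kept their side of 0 decide nothing. An unrecorded labelling or hybridisation batch cannot be told apart from differences between cultures, because no batch is given to compare with the 23.1% of variance on this component. No biological explanation other than age group was tested.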

How the results depend on the processing

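The alternatives that use the first component or leave out adult arrays 1 and 2, and the replicate block with an estimated correlation, were chosen after the results were seen. Under the alternatives that could be fitted, none of the called genes that were followed changed its direction on its own probe set. Where arrays were only left out this was fixed beforehand, since the groups compared did not overlap for any called probe set. TM4SF1, CDC25B, STX1A, SLC47A1, BBLN, NTRK2 and PLPP1 were not followed under them. For fetal minus adult the smallest called change was 1.58-fold, so that requiring at least 1.5-fold could not alter the count. With that alternative included, the count of 29 probe sets stayed within 1.5 times under 8 alternatives, such as 38 with median centring and 28 without the newborn arrays. It became 197 without flat probe sets, 120 with array weights, 221 with the replicate block, 16 with only the 2 groups compared, 44 with adult arrays 1 and 2 left out and 65 over only the arrays above 0 on the first component, and it ranged from 4 to 153 on leaving out 1 array. For infant minus adult the 4 became 53 without flat probe sets, 8 with a trended robust prior, 10 with array weights, 9 with the replicate block, 2 with only the 2 groups compared, 39 with the first component as a block, 44 with adult arrays 1 and 2 left out, 34 and 10 over only the arrays below and above 0 on it, and 0 to 55 on leaving out 1 array. For fetal minus infant the 0 became 1 without dim probe sets, 36 without flat ones, 1 with array weights, 1 with 1 probe set per gene, 2 with the replicate block, 5 without the newborn arrays and 0 to 21 on leaving out 1 array. For any age group the 8 became 176 without flat probe sets, 25 with a trended robust prior, 63 with array weights, 101 with the replicate block, 16 without the newborn arrays, 30 with the first component as a block, 28 with adult arrays 1 and 2 left out, and 2 to 95 on leaving out 1 array. For newborn minus gestation day 120 the 0 stayed 0 under all alternatives except on leaving out 1 array, where it ranged from 0 to 2, and the 2 came without fetal array 3, with fetal array 4 as the single newborn array. Fewer probe sets are tested without flat ones, and the filter uses the variance that the prior is fitted to. With adult arrays 1 and 2 left out, or over only the arrays above 0 on the first component, adult array 3 is the single adult array. It is assumed to vary like the arrays of the other groups, so the counts of both alternatives against adults rest on it. The cause of the other moves was not tested. The replicate numbers did not pair fetal with other arrays by the check used. Not every fetal array correlated best with the array of its own number, which held for arrays 1 and 4 against infants and for arrays 1 and 2 against adults. For infant minus adult, where they passed that check, the replicate block ended no call of a named gene or list.

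The 7 lists called for fetal minus adult became 0 with an estimated correlation, 3 with fry, 4 by ranks and 11 with adult arrays 1 and 2 left out. The 2 for infant minus adult became 0 with an estimated correlation, 0 with fry, 8 with the replicate block, of which 0 held with an estimated correlation as well, 4 with the first component as a block, 8 with adult arrays 1 and 2 left out and 3 to 5 on leaving out 1 array. The 11 for fetal minus infant became 0 with an estimated correlation, 1 with fry and 7 with the mean of all probe sets of a gene. The list counts with adult arrays 1 and 2 left out rest on 1 adult array as well. With the first component as a block the shift of the ribosomal list for fetal minus infant turned to 0.060. Over the named genes, 2661 values kept direction and side of the threshold, 173 fell short of it, 64 newly passed it and 88 turned sign, and over the called lists 239, 78, 0 and 1. Apart from COL6A1 and IGHM, whose other probe sets differed, the values that turned sign belonged to genes that had not passed, and the cause was not tested. Signal over background limits what can be seen, since probe sets of human sequence may read monkey transcripts weakly. The median log2 intensity was 7.38, and probe set means had a 10th percentile of 6.86 and a 90th of 8.81.

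In fetal minus adult the sign turned with array weights for HBQ1 -0.017. In fetal minus adult the sign turned without the newborn arrays for CD14 0.0073. In fetal minus adult the sign turned with the side of the first component as a block for ENG -0.13, THY1 -0.14, PTPRC -0.11, CD14 0.069 and HBD 0.041. For fetal minus adult the sign turned with adult arrays 1 and 2 left out for ENG -0.075, PTPRC -0.029, CD14 0.21 and HBD 0.021. For fetal minus adult the sign turned over only the arrays above 0 on the first component for ENG -0.075, PTPRC -0.029, CD14 0.21 and HBD 0.021. These are the same values by construction, since both settings compare the same fetal arrays with adult array 3. Other probe sets of the gene went the opposite way for fetal minus adult in COL6A1 -0.052, COL6A1 -0.055, IGHM 0.066, MEG3 -0.022, PLAGL1 -0.12, SLC2A1 -0.18, HSPH1 -0.034, CD44 -0.062, PTPRC -0.088, HBB -0.069 and HBE1 0.12. Leaving out 1 array turned the sign in at least 1 fit for fetal minus adult, with the ranges XIST from -1.62 to 0.36 and HBQ1 from -0.089 to 0.096. In infant minus adult the sign turned with array weights for THY1 0.056. In infant minus adult the sign turned with the replicate block for NT5E -0.015 and HBE1 -0.024. In infant minus adult the sign turned with adult arrays 1 and 2 left out for ENG -0.14 and CD14 0.039. For infant minus adult the sign turned over only the arrays below 0 on the first component for ENG -0.013, NT5E -0.048 and HBE1 -0.054. For infant minus adult the sign turned over only the arrays above 0 on the first component for THY1 0.17. Other probe sets of the gene went the opposite way for infant minus adult in NR4A3 -0.13, THY1 0.069, THY1 0.13, CD44 -0.12, CD44 -0.13, CD44 -0.039 and PTPRC 0.065. Leaving out 1 array turned the sign in at least 1 fit for infant minus adult, with the ranges NT5E from -0.041 to 0.073, HBE1 from -0.036 to 0.080, THY1 from -0.19 to 0.14, XIST from -1.94 to 0.039 and PTPRC from -0.17 to 0.078. In fetal minus infant the sign turned with quantile normalisation again for ENG -0.024. In fetal minus infant the sign turned without the newborn arrays for HBB -0.00066 and HBQ1 0.060. For fetal minus infant the sign turned with the side of the first component as a block for ENG -0.17, THY1 -0.023 and XIST -0.48. For fetal minus infant the sign turned over only the arrays above 0 on the first component for ENG -0.19, THY1 -0.12 and PTPRC -0.013. Other probe sets of the gene went the opposite way for fetal minus infant in MICAL2 -0.12, AURKA -0.089, COL6A1 -0.017, COL6A1 -0.038, COL6A1 -0.19, COL6A1 -0.030, ACTA2 0.033, OAS2 0.052, MEG3 -0.12, GRB10 -0.0022, PKM -0.039, SLC2A1 -0.12, RPS14 0.021, CD44 -0.22, CD44 -0.023, PTPRC -0.039, PTPRC -0.0045 and HBB -0.14. Leaving out 1 array turned the sign in at least 1 fit for fetal minus infant, with the ranges ENG from -0.043 to 0.17, HBD from -0.011 to 0.14 and HBB from -0.0051 to 0.071.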

Other observations

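The descriptions of named genes outside the rule, and the choice of component genes, were made after the values were seen, whereas the tests over other splits were planned, apart from the count over the 34 regroupings that part pairs.

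Some lists held genes that moved both ways between fetal and adult arrays. BMP and TGF-beta signalling, which steers bone and cartilage formation, was not called in 1 direction (camera adjusted p = 0.379), but fry's mixed test gave an adjusted p of 3.49e-05. Of its 24 members 12 were higher and 12 lower, ID3 passed over all genes, and 7 passed adjusted over the list alone, 5 higher and 2 lower. Matrix proteins and matrix enzymes other than collagens were not called either (camera adjusted p = 0.524, fry mixed adjusted p = 0.000338), with 3 higher and 4 lower of the 7 that passed adjusted over the list alone. Collagens had 3 such members, all higher, and 10 of 18 members lower (camera adjusted p = 0.725, fry mixed adjusted p = 0.0108).

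Among the genes with the largest loadings on the first component, 6 picked after their values were seen are given here. Others with such loadings included XIST and RPS4Y1, which set adult array 3 apart, IGLC1, which was high in adult arrays 1 and 2, and RPL38. ACAN, the core protein of the cartilage proteoglycan aggrecan, read 8.96 and 8.52 in adult arrays 1 and 2, 12.51 in adult array 3, 11.08 and 11.16 in infant arrays 1 and 2, 9.88, 10.98 and 10.92 in fetal arrays 1 to 3 and 12.59 in fetal array 4 by 1 of its probe sets. LGR5, an R-spondin receptor, read 6.84 and 7.00 in adult arrays 1 and 2 and 11.72 in adult array 3, but infant arrays 1 and 2, at 8.71 and 8.87, lay close to fetal array 1 at 8.89. IGFBP5, an insulin-like growth factor binding protein, read 9.23, 9.63 and 12.13 in the adult arrays, 9.70 and 9.12 in infant arrays 1 and 2 and 8.86 in fetal array 1. The cytokine gene IL6 read 8.09, 8.63 and 10.15 in the adult arrays, 8.66 and 8.99 in infant arrays 1 and 2 and 8.67 in fetal array 1. For ACAN, IGFBP5 and IL6 the arrays on the 2 sides of the component thus overlapped. FOLR1, a folate receptor, read 10.25 and 8.34 in adult arrays 1 and 2, 9.24 in infant array 1 and 11.36 in infant array 2, against 7.01 in adult array 3. DCN, the matrix proteoglycan decorin, read 12.36 and 12.71 in adult arrays 1 and 2 and 11.19 in adult array 3.

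The arrays of each pair of groups were split in every other way into groups of the same sizes. Chance could not be excluded for the 29 probe sets between fetal and adult arrays, as 2 of 35 splits gave as many, with 88 as the highest other, a split that placed fetal array 4 with the adults. It could not be excluded for the 7 lists there (11 of 35 splits, highest other 12). Between infant and adult arrays 4 of 35 splits gave as many as the 4 probe sets, with 387 as the highest other, and 24 of 35 as many as the 2 lists, with 10 as the highest other. That split into 387 separates the arrays as the first component does and points to a structure of the samples. Among the 8 splits that part infant and adult arrays of the same number, too few for a share under 0.05, the real one gave 4 probe sets and 2 lists. The others gave at most 1 and 10. Between fetal and infant arrays all 35 of 35 splits gave at least the 0 probe sets, which a count of 0 fixes beforehand, so that share decides nothing. The highest other gave 42, where fetal array 4 and infant array 3 changed places. There 2 of 35 splits gave as many as the 11 lists, with 12 as the highest other. Over all age groups, 3 of 100 free regroupings, the real one included, gave as many as the 8 probe sets, with 45 as the highest other. This share lay under the bound of 0.05, alone among the planned tests over splits, which were not corrected for their number. Free regrouping also treats the arrays as exchangeable. For these reasons chance is not excluded. Of the 34 regroupings that part all 3 infant and adult arrays of the same number, the real one included, 1 gave as many, and the highest other gave 2. Without adult array 1 the 8 became 2.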
